A study of Mus musculus with 12 samples.

How the data were processed

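RNA was isolated from the organoids and polyA-selected before library preparation, per the labels' protocols. The deposited table holds expected counts per gene, by its header and name. The submitters' processing notes name cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and the GRCm38 mouse genome, without the role or settings of each tool. The annotation release and the strandedness of counting are not given in the sources used here, so antisense and overlapping genes cannot be told apart, and genes with near-identical copies are uncertain. The values were already whole numbers in the table, so rounding changed nothing. Of 55426 rows, 5 are transgene sequences, which held 2 counts in all, in antral vehicle line 8028, and were left out; 55421 gene rows remained. Gene positions below are from GENCODE mouse release 21 on the same build, where 55154 identifiers matched.

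Groups follow the sample labels. The treatment label of vehicle samples reads as none, while the protocol gives a vehicle, and the labels state XAV939 at 1 mM, far above the doses usual in culture, which is repeated here only as labelled. The 3 lines per region are described as independent; nothing says whether a number shared by corpus and antrum marks the same mouse. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom 10.0 to 280).

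Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, the filterByExpr filter by group, which left 16152 genes, and a robust quasi-likelihood fit of all 12 libraries with 8 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05 and no minimum fold. The fit gave log2 fold changes with standard errors. CPM values use TMM-scaled totals. Ratios of summed counts carry 95% exact intervals that cover counting error only. The 29 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 116 tests (29 lists in 4 comparisons). The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

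Named genes were the 6 largest rises and 6 largest falls per treatment comparison with an adjusted p below 0.05, a mean of at least 5 CPM and the same direction in all 3 lines; 22 fixed genes, of which 19 were measured; up to 3 members of each list that passed; the 5 largest differences between regions in each direction; and, for antrum against corpus in vehicle, the 6 largest each way without overlap of the groups and the members of the regional identity lists. In all 51 genes were named for corpus and 45 for antrum. Results of some genes that the rule names are not reported here.

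Line numbers pair the vehicle and inhibited libraries of a region, since the protocol treats the same lines both ways: deviations of the 6 same-line pairs from their group means correlated at 0.157 to 0.544. Across regions same-numbered pairs correlated at -0.104 to 0.277 and were not taken as pairs.

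Alternatives were RLE, upper quartile and total-count scaling, no low-count filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a block on the line, only the 6 libraries compared, and leaving out each library or line. For lists they were an estimated correlation, the fry test, the block and RLE scaling; calls of list members under each scaling and with the block, and the aryl hydrocarbon receptor targets and NRF2 genes apart, were added after seeing the data. On data simulated for the corpus comparison over 15859 genes, the test recovered 50.7% of genes changed 1.5-fold, 85.1% changed 2-fold and 98.5% changed 4-fold, with 10 false calls among 166 and 0 calls in the unchanged antrum. Changes were placed only in well-counted genes and in a small share of all genes, without differences between lines. The recovery may therefore not hold for low-count genes or for the other comparisons.

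On GRCm38, Lgr5 (ENSMUSG00000020140) lies on chromosome 10 from 115450311 to 115587780, Axin2 (ENSMUSG00000000142) on chromosome 11 from 108920349 to 108950783, Muc5ac (ENSMUSG00000037974) on chromosome 7 from 141788972 to 141819231, Muc6 (ENSMUSG00000048191) on chromosome 7 from 141633456 to 141655319, Cyp1a1 (ENSMUSG00000032315) on chromosome 9 from 57687928 to 57703824, Akr1c14 (ENSMUSG00000033715) on chromosome 13 from 4049011 to 4090688 and Irx5 (ENSMUSG00000031737) on chromosome 8 from 92357625 to 92376286. All are annotated as protein-coding, and counts are sums over the whole gene.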

Results

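Messenger RNA was measured in wild-type mouse stomach organoids, 3-dimensional cultures grown from isolated gastric glands, in 12 libraries that fall into 4 groups of 3. The groups combine the region of origin, corpus (the body of the stomach) or antrum (its outlet end), with either vehicle or Wnt inhibition. Each region was represented by 3 lines, numbered 8025, 8026 and 8028. Inhibition began on day 4 after passage and lasted 24 h. It combined XAV939, a tankyrase inhibitor that lowers Wnt signalling, with withdrawal of added Wnt and R-spondin and with Noggin, a blocker of bone morphogenetic proteins, at 100 ng/mL. Vehicle libraries stayed in normal medium with 50% L-WRN, a conditioned medium from cells that secrete Wnt, R-spondin and Noggin. The compound and the change of medium therefore cannot be separated, and the serum in the treated medium is not stated. The growth medium held 20% serum for corpus and 10% for antrum, so region and serum cannot be separated either. Library totals ranged from 18858022 to 31656696 counts, and a count of 3, the most that a reading of 0 allows, equals 0.0948 to 0.159 CPM, the count scaled to a common library total. Intervals and limits from counts cover counting error only.

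The first principal component held 48.4% of the variance and parted the 6 inhibited from the 6 vehicle libraries. The second held 18.6% and followed region, except that both libraries of corpus line 8028 lay towards antrum, at 1.8 and -25.3 against 28.2 to 40.9 for the other corpus libraries. The rRNA-like genes CT010467.1, AY036118, Lars2 and Gm26917 took 17.2% of the counts in antral vehicle line 8025 and 6.87% in antral vehicle line 8028, and 0.839% to 3.46% in the other libraries.

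**Figure D1:**
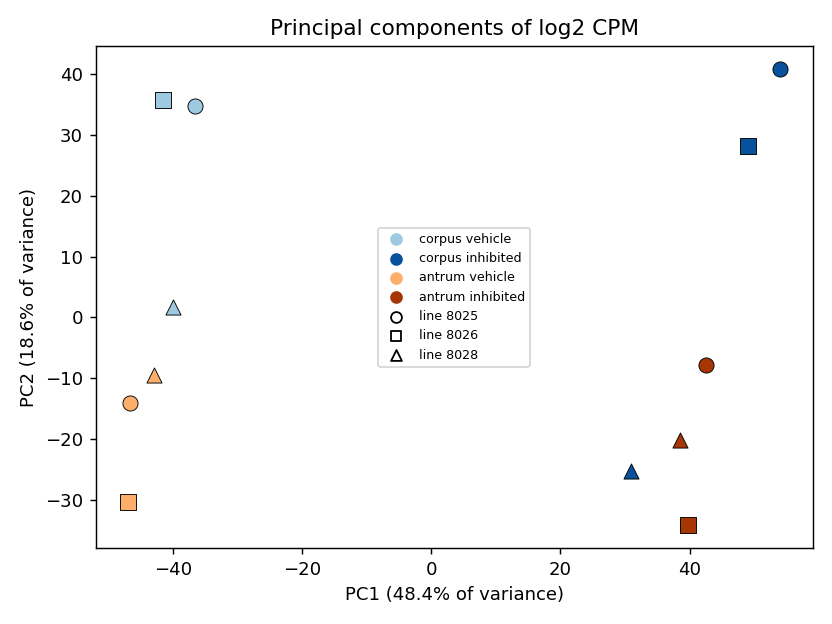
Principal component scores of the 12 libraries computed from log2 CPM, with color for group and marker shape for line; each axis gives its share of variance. The inhibited libraries lie at 30.9 or above on the first component and the vehicle libraries at -36.5 or below, and corpus line 8028 (triangles in blue) lies nearer the antral libraries than the other corpus lines on the second.

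The first comparison asked which genes Wnt inhibition changed in corpus organoids. Lgr5, a receptor for R-spondin and a stem cell marker, fell from 48.2 ± 5.05 to 1.00 ± 0.781 CPM (SD, n = 3), and Axin2, a feedback inhibitor of Wnt signalling, fell from 68.8 ± 4.00 to 9.28 ± 8.23 CPM. Inhibited line 8028 kept the most Axin2, at 18.7 CPM against 3.71 and 5.39 in lines 8025 and 8026. The surface mucin gene Muc5ac rose from 0.814 ± 0.708 to 42.4 ± 26.2 CPM and the trefoil gene Tff1 from 215 ± 47.3 to 2096 ± 685 CPM. The gland mucin gene Muc6 fell from 203 ± 56.5 to 12.3 ± 3.94 CPM. Cyp1a1, a target of the aryl hydrocarbon receptor, went from 4 counts in the 3 vehicle libraries to 2690 in the 3 inhibited ones, a depth-corrected ratio of 862 (95% counting interval 336 to 3170). All 4 vehicle counts of Cyp1a1 lay in line 8025, so the ratio rests on that library. These genes moved in the same direction in all 3 lines, with edgeR adjusted p from 2.50e-06 for Cyp1a1 to 0.000513 for Axin2.

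Of the 19 measured Wnt target genes 18 fell in corpus, among them Sp5 (log2 change -2.92 ± 0.201 SE) and Nkd1 (-3.57 ± 0.454); the list had a camera adjusted p of 5.71e-10, and an adjusted p = 0.483 with an estimated correlation. Adjusted over the list alone, 19 fell. Of 18 stem and progenitor genes 11 fell and 1 rose (adjusted p 0.00028; adjusted p = 0.483 with an estimated correlation; 13 and 2 adjusted over the list alone), with Aqp5 at -2.92 ± 0.206 and Tnfrsf19 at -4.63 ± 0.404. The stem and progenitor list shares Lgr5, Axin2, Tnfrsf19, Cd44, Sox9, Ascl2 and Smoc2 with the Wnt target list, so the lists are not separate evidence. All 12 measured surface mucous pit genes rose, also adjusted over the list alone, including Mucl3 (4.55 ± 0.272), Gkn2 (3.78 ± 0.571) and Foxq1 (1.20 ± 0.092), with an adjusted p of 1.15e-08 and an adjusted p = 0.483 with an estimated correlation. Gkn1 also rose (1.84 ± 0.497, adjusted p 0.0158), but lost its call without vehicle line 8028 (adjusted p 0.056), inhibited line 8025 (0.0727), both libraries of line 8025 (0.134) or of line 8026 (0.0543), and without a low-count filter (0.0738).

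The 11 genes of the aryl hydrocarbon receptor and NRF2 list, which answer to foreign compounds and oxidative stress, all rose in corpus, also adjusted over the list alone (adjusted p 1.97e-06; adjusted p = 0.483 with an estimated correlation). Ahrr, a repressor of the receptor, changed by 3.84 ± 0.435 and Nqo1 by 2.37 ± 0.17 on the log2 scale. Of 20 cholesterol synthesis genes 16 rose (Hmgcs1 1.01 ± 0.12, Fdps 0.73 ± 0.076; 16 rose and 1 fell adjusted over the list alone), with an adjusted p of 4.50e-07 and an adjusted p = 0.483 with an estimated correlation. Of 11 endoplasmic reticulum stress genes 7 rose, with Chac1 at 1.51 ± 0.226 and Atf4 at 0.54 ± 0.092 (8 rose and 1 fell adjusted over the list alone; adjusted p 0.00622; adjusted p = 0.569 with an estimated correlation). Of 31 proliferation genes 2 fell, and 1 adjusted over the list alone, and 23 fell with the line as a block. The list mean of -0.585 had an adjusted p of 0.000271, an adjusted p = 0.733 with an estimated correlation, and 0.158 with fry, which tests for a shared direction without comparing other genes. Cenpf fell by 0.82 on the log2 scale (SE 0.192), a call lost without both libraries of line 8026 (adjusted p 0.0849). The other call, Top2a (adjusted p 0.0482), was lost without any single corpus library except inhibited line 8028 (0.071 to 0.156), and without both libraries of line 8025 or 8026 (0.125 and 0.22). It was also lost with only the 6 corpus libraries (0.132) and without a low-count filter (0.16). Mki67 stood at -0.62 ± 0.248 (adjusted p 0.0792), and passed with the line as a block (0.0113), with DESeq2 (0.0417), with limma-voom (0.0456), without inhibited line 8028 (0.00105) and without both libraries of that line (0.0037). It fell least in line 8028, from 368 to 314 CPM, against 295 to 131 in line 8025 and 315 to 189 in line 8026. With total counts the receptor targets Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1 kept their calls, as did 2 of the 6 NRF2 genes. With the same scaling 13 of 16 cholesterol genes, 4 of 7 stress genes and 10 of 12 pit genes kept their call, and 8 proliferation genes fell, as with upper quartile scaling. Under these and RLE scaling 0 called members of any list turned direction.

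Across corpus, 4985 of 16152 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2498 higher and 2487 lower, of which 534 and 836 changed at least 2-fold. With line as a block, 3821 were lower in place of 2487, and with scaling by total counts only the share of higher calls was 26.4% in place of 50.1%. Without both libraries of line 8026 the count was 2550, and without those of line 8025 it was 3238. It rose to 6010 without both libraries of line 8028, and to 6888 without the inhibited library of that line alone.

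**Figure D2:**
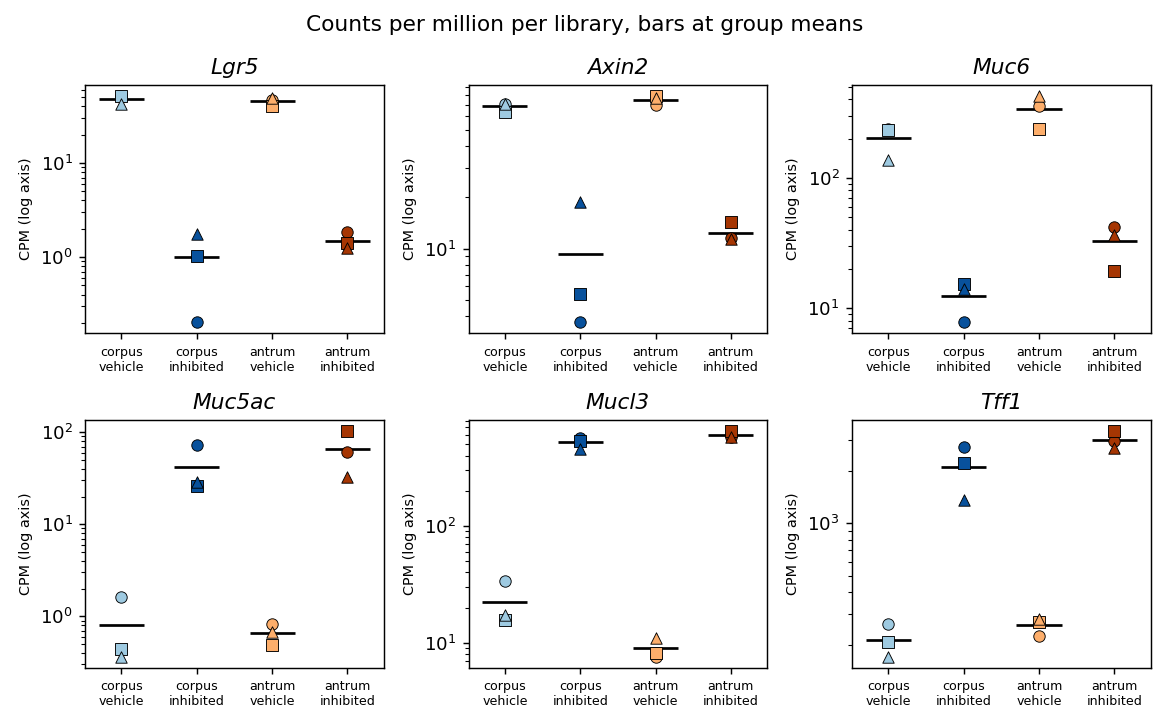
CPM per library (log axes) of 6 genes in the 4 groups, with marker shape for line (circle 8025, square 8026, triangle 8028) and bars at group means. Lgr5, Axin2 and Muc6 lie lower, and Muc5ac, Mucl3 and Tff1 higher, in all 3 inhibited libraries of each region than in its vehicle libraries.

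The second comparison asked the same of antral organoids. Lgr5 fell from 45.0 ± 4.51 to 1.5 ± 0.298 CPM (SD, n = 3) and Axin2 from 75.5 ± 4.74 to 12.4 ± 1.63 CPM. Muc5ac rose from 0.663 ± 0.166 to 65.6 ± 35.6 CPM, Tff1 from 259 ± 29.1 to 3019 ± 343 CPM and Mucl3 from 8.91 ± 1.84 to 603 ± 42.7 CPM. Muc6 fell from 339 ± 93.6 to 32.6 ± 12 CPM. Cyp1a1 went from 4 counts to 3366, a ratio of 742 (95% counting interval 290 to 2730). The edgeR adjusted p of these genes ran from 5.46e-07 for Mucl3 to 0.000864 for Axin2, and each moved in the same direction in all 3 lines.

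Of the 19 Wnt target genes 17 fell in antrum, also adjusted over the list alone (adjusted p 1.33e-08; adjusted p = 0.483 with an estimated correlation), with Tnfrsf19 at -4.74 ± 0.391 and Smoc2 at -4.59 ± 0.584. All 12 pit genes rose, also adjusted over the list alone (adjusted p 4.11e-10; adjusted p = 0.483 with an estimated correlation), with Krt20 at 3.44 ± 0.299. Of 18 stem and progenitor genes, which include the shared Wnt targets, 10 fell and 1 rose (11 and 2 adjusted over the list alone). The stem and progenitor list had a camera adjusted p of 0.00115, and an adjusted p = 0.497 with an estimated correlation. In the aryl hydrocarbon receptor and NRF2 list 8 of 11 rose, 10 adjusted over the list alone, with Nqo1 at 2.73 ± 0.173 and Tiparp at 1.63 ± 0.168 (adjusted p 3.42e-06; adjusted p = 0.483 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 20 cases and fell in 1 (15 and 2 adjusted over the list alone; adjusted p 3.94e-05; adjusted p = 0.548 with an estimated correlation). Intestinal genes rose in 5 of 12 cases, with Clca1 at 4.84 ± 0.451 and Tff3 at 3.48 ± 0.52 (5 rose and 1 fell adjusted over the list alone, and 9 rose and 1 fell with the line as a block; adjusted p 0.00686; adjusted p = 0.483 with an estimated correlation). Proliferation genes fell in 2 of 31 cases, Cenpf (-0.66 ± 0.191) and E2f1 (adjusted p 0.0404), and in 0 adjusted over the list alone (list adjusted p 0.00392; adjusted p = 0.736 with an estimated correlation; 0.285 with fry). With the line as a block 14 fell, among them Mcm7 (-0.72, adjusted p 0.0118 in place of 0.0741) and Mki67 (-0.49, adjusted p 0.0457 in place of 0.17), which were lower in all 3 lines. Mcm7 also passed with upper quartile scaling (0.0488) and DESeq2 (0.035), and both with only the 6 antral libraries (0.00434 and 0.0158). Cenpf lost its call without antral vehicle line 8026 (adjusted p 0.0699) or 8028 (0.0566) or inhibited line 8025 (0.0794) or 8028 (0.0714), and E2f1 without any single antral library (0.051 to 0.154). Both lost it without both antral libraries of any line (0.0873 to 0.195), without a low-count filter (0.0661 and 0.0709) and without the antral vehicle libraries of lines 8025 and 8028 (0.126 and 0.0925). With total counts 13 of the 16 cholesterol calls, 7 of the 8 receptor and NRF2 calls and 4 of the 5 intestinal calls were kept. The antral vehicle libraries of lines 8025 and 8028 carried 17.2% and 6.87% rRNA-like counts, beside all of these changes.

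In antrum 4794 of 16152 genes passed, 2636 higher and 2158 lower, with 621 and 715 changed at least 2-fold. With line as a block 3261 were lower in place of 2158. The share of higher calls was 43.6% with upper quartile scaling and 44.4% with total counts, in place of 55.0%. Without the antral vehicle libraries of lines 8025 and 8028, an alternative chosen after seeing the data that leaves 1 vehicle library assumed to vary like the other groups, 2740 genes passed. Without both libraries of line 8025 the count was 2710, and without those of line 8026 it was 2808.

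Retinoid metabolism genes, named in the study's title, moved both ways. Among the fixed genes, Adh7, which oxidizes retinol, rose in corpus from 94.1 ± 12.6 to 304 ± 61.5 CPM (SD, n = 3; adjusted p 0.000233) and in antrum from 60.7 ± 21.6 to 286 ± 34.0 CPM (adjusted p 3.94e-05). Rdh10, a retinol dehydrogenase, rose by 0.50 ± 0.099 in corpus and 0.37 ± 0.099 in antrum on the log2 scale, the antral call being lost without inhibited line 8025 (adjusted p 0.0681), without both libraries of any line (up to 0.0955), with total counts (0.0731) and without the antral vehicle libraries of lines 8025 and 8028 (0.116). Aldh1a3, a retinaldehyde dehydrogenase, rose in corpus by 1.64 ± 0.393 (adjusted p 0.0086, but 0.102 without both libraries of line 8026) and passed in antrum at 1.22 ± 0.399 (adjusted p 0.0393). In antrum leaving out any single antral library except inhibited line 8028 ended the call (adjusted p up to 0.169), as did leaving out both libraries of any line (0.0959 to 0.201), total counts (0.0517), no low-count filter (0.105) and limma-voom (0.0778), with 0.237 the highest, without the vehicle libraries of lines 8025 and 8028. Aldh1a1 stood at -0.37 ± 0.17 and -0.34 ± 0.171 and did not pass (adjusted p 0.123 and 0.163). It passed in corpus with line as a block (0.0238), with total counts (0.0324), without inhibited line 8025 (0.0136) and without both libraries of that line (0.0346), and in antrum with only the 6 antral libraries (0.00385). Reads can be shared with its close paralog Aldh1a7, which was looked at after the values were seen. Aldh1a7 passed at -0.407 in corpus and -0.414 in antrum on the log2 scale (edgeR adjusted p 0.0347 and 0.034). In corpus that call was lost without any single corpus library except inhibited line 8025 (0.069 to 0.137). It was also lost there without both libraries of line 8026 or 8028 (0.174 and 0.201) and with only the 6 corpus libraries (0.069). In antrum the Aldh1a7 call was lost without vehicle line 8026 or 8028 or inhibited line 8025 or 8026 (0.0699 to 0.132). Leaving out both antral libraries of any line also ended it (0.112 to 0.123). Named after their values were seen, Stra6, a membrane receptor for retinol uptake, stood at -3.36 ± 0.25 in corpus and -3.32 ± 0.251 in antrum (adjusted p 5.1e-06 and 5.22e-06), and Rbp2, a retinol-binding protein of the intestine, rose from 15 to 322 counts in corpus (ratio 27.5, 95% counting interval 16.4 to 49.8) and from 5 to 739 in antrum (ratio 130, interval 55.6 to 403). Without single libraries the log2 change of Rbp2 ran from 3.961 to 5.018 in corpus and from 6.395 to 8.312 in antrum, with its calls kept. Over the 24 measured members 6 rose and 5 fell in corpus and 8 rose and 3 fell in antrum, and 6 and 5, and 10 and 3, adjusted over the list alone. As a list they did not pass (camera adjusted p 0.229 and 0.0977; adjusted p = 0.609 and 0.483 with an estimated correlation), while fry gave 0.024 and 0.00188. In antrum 9 of the 11 calls were kept with upper quartile scaling and 8 with total counts.

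**Figure D3:**
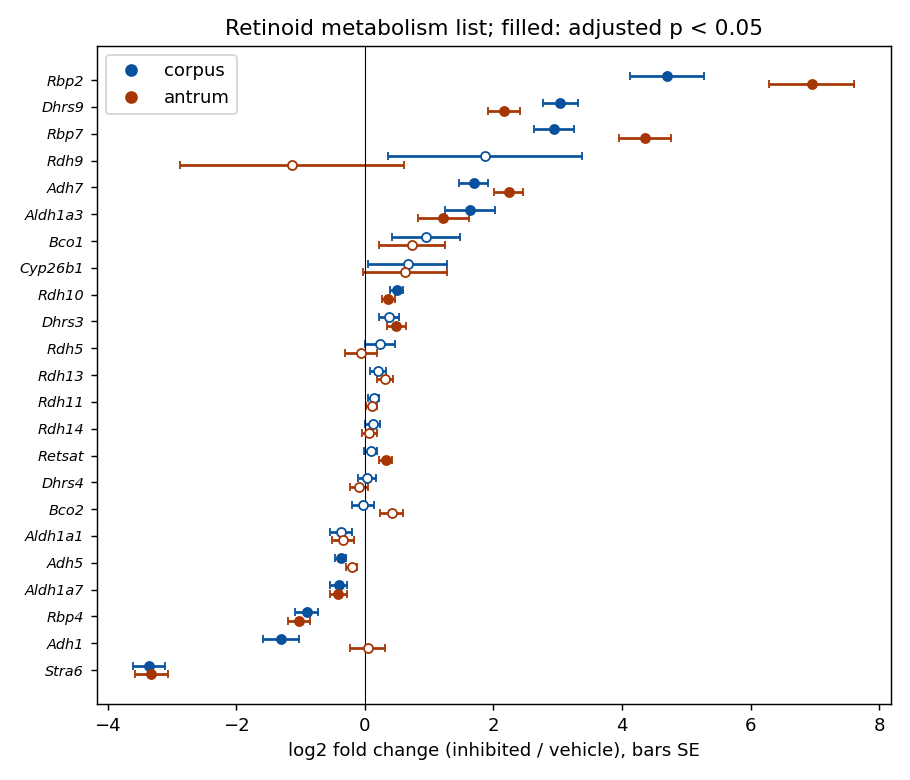
Log2 fold change with its SE for the measured retinoid metabolism genes reported here, inhibited over vehicle, in corpus (blue) and antrum (brown), with filled points for adjusted p below 0.05. Stra6 lies lowest, at -3.36 and -3.32, and Rbp2 highest, at 4.70 and 6.95.

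Pgc, the pepsinogen C precursor, fell from 120 ± 55.2 to 13.0 ± 2.00 CPM in corpus and from 62.4 ± 13.0 to 18.5 ± 9.42 CPM in antrum (SD, n = 3; adjusted p 0.000235 and 0.00772), and the antral call was lost without both libraries of line 8025 (adjusted p 0.076) or without the vehicle libraries of lines 8025 and 8028 (0.11). Cblif, which encodes gastric intrinsic factor, fell 31.2-fold in corpus (adjusted p 2.14e-05). In antrum it was lower in every line, at 2.11 to 6.38 CPM in inhibited against 32.9 to 61.4 in vehicle libraries. In the chief cell list 2 of 6 fell and 1 rose in each region (3 fell in corpus and 2 in antrum adjusted over the list alone, with 1 rising), and the list did not pass (camera adjusted p 0.33 and 0.635). In the mucous neck and gland list 6 of 10 fell and 2 rose in corpus (Muc6 fell, Tff2 rose by 2.26 ± 0.359), and 5 fell and 3 rose in antrum; adjusted over the list alone 6 fell in each region, with 2 and 3 rising. The list did not pass in either (camera adjusted p 0.114 and 0.3; fry 0.00111 and 0.0243). Chga, an endocrine marker, was at 0.328 ± 0.0291 CPM in antral vehicle and 0.324 ± 0.241 CPM in antral inhibited libraries and did not pass (adjusted p 0.994).

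The regions were then compared in their response. Of the calls, 2078 genes were higher in both regions, against 408 for independent lists, 1683 were lower in both, against 332, and 0 went in opposite directions. Corpus line 8028, which lay towards antrum on the second principal component, is included here, and the overlap without it was not computed. The log2 changes correlated across the 16152 genes with r = 0.823 and rho = 0.787, and r = 0.935 for the 11031 genes at 5 CPM or more; genes are not independent replicates. In the test of the difference 1 gene passed, Akr1c14, an aldo-keto reductase, which rose from 2.61 ± 0.521 to 32.4 ± 4.25 CPM in antrum and from 11.4 ± 2.19 to 29.1 ± 0.912 CPM in corpus (SD, n = 3; difference in log2 change 2.27 ± 0.227, adjusted p 0.00963). It belongs to a family of similar genes whose reads can be shared, and its call was lost without corpus inhibited line 8026 (adjusted p 0.0689), without both libraries of corpus line 8025 or 8026 or of antral line 8026 or 8028 (0.0815 to 0.138), and without the antral vehicle libraries of lines 8025 and 8028 (0.129). At an unadjusted p of 0.05 638 of the 16152 genes passed, fewer than the share of 0.05 that would pass with no difference at all. Such a shortfall does not show that the regions responded equally. The main fit had no block on the line, so differences between lines stayed in its spread. Deviations of same-line pairs correlated at 0.157 to 0.544. DESeq2 called 9, limma-voom 1, and edgeR with line as a block 7. Leaving out corpus inhibited line 8026 gave 0, corpus inhibited line 8028 gave 5, and antral vehicle or inhibited line 8028 gave 2. Without both libraries of corpus line 8028 the test gave 3.

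**Figure D4:**
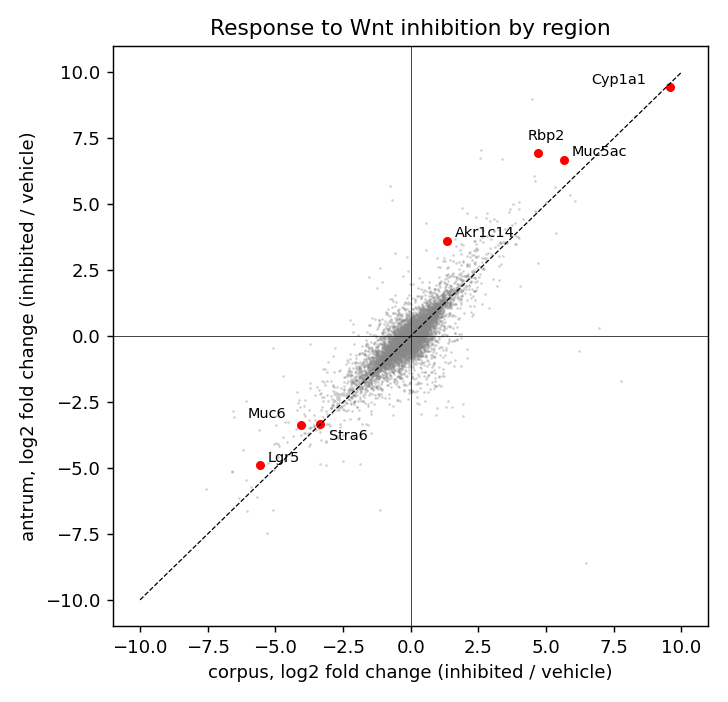
Log2 fold change of each of 16152 genes with inhibition, corpus on the horizontal and antrum on the vertical axis, with the line of equal change dashed and 7 genes marked in red. Cyp1a1 lies near that line at 9.59 and 9.43, and Akr1c14 above it.

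The last comparisons set antrum against corpus. In vehicle, Irx5, a homeobox gene of the corpus list, had 835 counts in corpus and 4 in antrum (ratio 156, 95% counting interval 60.8 to 575; adjusted p 0.0458), with 2.13 CPM in corpus line 8028 against 12.9 and 10.7 in the other corpus lines. Akr1c14 was 4.31-fold lower in antrum (adjusted p 0.00119), and the drug-metabolism genes Aldh3a1 and Gstm1 were at -1.14 ± 0.172 and -0.78 ± 0.132 on the log2 scale (Gstm1 has close paralogs). The sterol gene Fdps was higher in antrum by 0.55 ± 0.076. These last 3 calls were each lost without either of corpus lines 8025 and 8026 or without antral line 8025 (adjusted p 0.108 to 0.206), without both vehicle libraries of line 8025 or 8026 (0.179 to 0.426), and without the antral vehicle libraries of lines 8025 and 8028 (0.0903 to 0.222). Leaving out antral line 8026 ended the calls of Aldh3a1 and Gstm1 (0.0749 and 0.0928), and leaving out antral line 8028 that of Fdps (0.0506). Gstm1 also lost its call with RLE (0.0529), upper quartile (0.0591), limma-voom (0.0513), the number as a block (0.0629) and at least 1 CPM in 3 libraries (0.0535), Fdps with total counts (0.0696), and all 3 with only the 6 libraries compared (0.0637 to 0.0712). Nkx6-3, an antral homeobox gene, had 66.0 ± 4.28 CPM in antrum and 16.8 ± 27.7 in corpus (SD, n = 3), with 48.7 CPM in corpus line 8028 and 0.296 and 1.24 in the other corpus lines, and did not pass (edgeR adjusted p 0.536). Without corpus line 8028 its edgeR adjusted p was 0.0035. That line was left out after it was seen to stand apart on these same genes, so this value is not separate evidence. Of 20 cholesterol synthesis genes 2 were higher in antrum, and 18 adjusted over the list alone (camera adjusted p 9.40e-15; adjusted p = 0.483 with an estimated correlation); with total counts 0 passed singly, and with RLE or upper quartile scaling 1 did. Corpus identity genes were lower in 1 of 5 cases, and in 4 adjusted over the list alone (adjusted p 4.71e-05; adjusted p = 0.483 with an estimated correlation). Endoplasmic reticulum stress genes passed as a list towards antrum with 0 of 11 called, and 5 adjusted over the list alone (adjusted p 0.000166; adjusted p = 0.483 with an estimated correlation; 0.0716 without the antral vehicle libraries of lines 8025 and 8028). Proliferation and antral identity genes passed towards antrum (adjusted p 0.0176 and 0.0451) and p53 targets towards corpus (0.0451), each with 0 members called, and with adjusted p = 0.741, 0.539 and 0.684 with an estimated correlation and 0.648, 0.113 and 0.285 with fry; antral identity genes stood at 0.0533 with RLE scaling.

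In inhibited libraries the goblet cell gene Clca1 stood 3.06 ± 0.406 higher on the log2 scale in antrum, and 3.73 higher without corpus line 8028. Irx5 had 709 counts in corpus and 1 in antrum (ratio 772, 95% counting interval 138 to 30500). The adjusted p in all libraries was 0.0423 for both genes. Both calls were lost without each single inhibited library except corpus line 8028 (0.0977 to 0.284), and without both inhibited libraries of line 8025 or 8026 (0.279 to 0.849). They were also lost with only the 6 libraries compared (0.321 for both), with total counts (0.0811 and 0.072) and without a low-count filter (0.129 and 0.13). Irx5 also lost its call with upper quartile scaling (0.0547) and limma-voom (0.404). In vehicle 32 genes passed, 11 higher and 21 lower in antrum, and in inhibited libraries 10 passed, 8 higher and 2 lower. The vehicle split was 7 higher and 54 lower with total counts. It was 39 and 6 without antral line 8026, where 12 of the 32 calls were kept, and 6 and 26 without antral line 8028, also with 12 kept. The vehicle count was 1 without corpus line 8025, corpus line 8026 or antral line 8025, and 70 without corpus line 8028; the inhibited count was 0 or 1 without any library except corpus line 8028, and 1883 without that. Akr1c14 kept its vehicle call without each single library, and lost it without the antral vehicle libraries of lines 8025 and 8028 (adjusted p 0.0708), where 2 genes passed. Irx5 lost its vehicle call without each single vehicle library except corpus line 8028 (adjusted p 0.0786 to 0.182), and without both vehicle libraries of line 8025 (0.401) or 8026 (0.292). It also lost it with limma-voom (0.23), without a low-count filter (0.0936), with only the 6 libraries compared (0.0865) and without the antral vehicle libraries of lines 8025 and 8028 (0.247). DESeq2 called 497 and 149. Without both libraries of corpus line 8028, an alternative chosen after seeing that the line stood apart on these same genes, 1080 and 2386 genes passed.

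**Figure D5:**
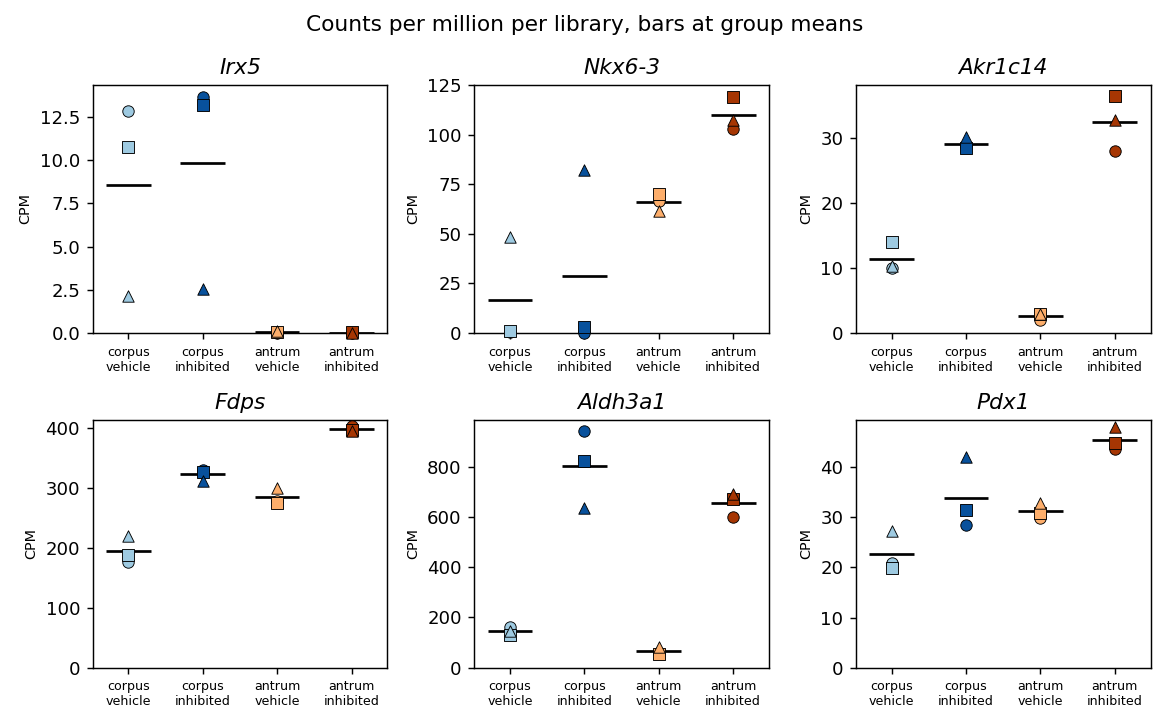
CPM per library (linear axes from 0) of 6 genes in the 4 groups, with marker shape for line (circle 8025, square 8026, triangle 8028) and bars at group means. Irx5 in corpus line 8028 lies at 2.13 and 2.56 CPM, below the other corpus lines, and Nkx6-3 in that line at 48.7 and 82.5 CPM, above them.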

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

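The tests of explanations in these paragraphs were chosen after the results were seen; the counts over other splits of the samples were planned.

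Akr1c14 and 7 gene lists were singled out because the test of the difference between regions passed. For Akr1c14 the log2 change with inhibition was larger in antrum by 2.265. The mean difference over list members was 0.277 for Wnt targets, 0.635 for surface mucous pit genes, 0.633 for mucous neck and gland genes, -0.278 for endoplasmic reticulum stress genes, -0.107 for cholesterol synthesis genes and 0.204 for mitochondrially encoded genes. For the 2 measured mesenchymal genes, Col1a1 and Vim, both below 1 CPM in every group, it was -2.014. With an estimated correlation 0 of the 29 lists passed in this comparison, where the lowest adjusted p = 0.379, and with fry 1 did, the mesenchymal genes (0.00771), with the other 6 at 0.113 to 0.518. Without the antral vehicle libraries of lines 8025 and 8028 the camera adjusted p was 0.324 for Wnt targets, 0.0629 for stress genes and 0.262 for cholesterol genes, and without corpus line 8028 it was 0.0735 for pit genes. Groups of 3 are too small for the test for outlying samples.

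Each comparison of 3 against 3 samples allows 10 splits, too few for a share under 0.05. The real split called 4985 genes in corpus against at most 0 in other splits (1 of 10 as large), 4794 in antrum against at most 1, 32 and 10 between regions against at most 0, and 1 for the difference in response against at most 0. Among splits that, like the real one, part all 3 pairs, the other 3 called 0 genes in corpus and in antrum. Every other split mixes the compared groups, which puts their difference into the spread within groups. Few calls in those splits therefore do not argue against chance.

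On the second principal component the vehicle library of corpus line 8028 (1.8) lay between the other corpus libraries (28.2 to 40.9) and the antral ones (-34.2 to -7.9), and its inhibited library (-25.3) among the antral ones. Antral cells mixed into the line in 1 share would give that share alike from genes higher in antrum and genes higher in corpus. That holds only if its corpus cells matched the other corpus lines. The median antral shares from these gene sets were 0.539 (quartiles 0.243 to 0.695, 11 genes) and 0.827 (0.823 to 0.828, 5 genes) in the vehicle library. In the inhibited library they were 0.67 (0.532 to 0.742, 6 genes) and 0.939 (0.835 to 1.005, 6 genes). The quartiles cover the spread between few genes, not the variation between lines, so these shares do not decide and a mix stays open. Libraries like those of the 3 antral lines under a corpus label are argued against by the corpus identity genes that part the other corpus lines from antrum: 4 of 4 in the vehicle and 3 of 3 in the inhibited library (100%) lay above every antral library by their counting interval, with Irx5 at 64 and 68 counts against at most 3, Irx2 at 25 and 13 against at most 2 and Irx3 at 65 and 45 against at most 24. The remaining vehicle gene, Cblif, was close, at 68.9 CPM (lower counting limit 66) against at most 61.4 in antrum. Atp4a, at 0.799 and 0.188 CPM against at most 1.54 in antrum, did not part the regions and was not counted. Cblif was not counted in the inhibited library for the same reason. The argument therefore rests on Irx2, Irx3 and Irx5. Of corpus genes chosen in the other treatment, 80% of 5 in the vehicle and 50% of 6 in the inhibited library lay above the highest antral library of that treatment. A line that itself is intermediate in regional identity, and an antral sample unlike these 3 lines, were not tested and stay open.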

How the results depend on the processing

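The alternatives without corpus line 8028, without the antral vehicle libraries of lines 8025 and 8028, without the rRNA-like genes, with calls of list members under each scaling and with the block, with receptor targets and NRF2 genes apart, and with an estimated correlation together with the block or with these libraries left out were chosen after seeing the data; the others were planned. Expected counts without rounding could not be run because the values are whole numbers. Where no cause is named, the cause was not tested.

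The corpus and antral counts stayed within 1.5 times of 4985 and 4794 under each other scaling, filter and tool and with line as a block (7022 and 6594). Leaving out libraries gave 2550 to 6888 and 2710 to 4207, with fewer samples, and 2740 without the 2 antral vehicle libraries. Relative to TMM, where the median log2 change over all genes was -0.037 in corpus and -0.044 in antrum, total counts moved it to -0.193 and -0.119. The difference in response gave 9 genes with DESeq2, 7 with the replicate block and 0 to 5 with libraries left out. Antrum against corpus in vehicle gave 17 with RLE, 18 with upper quartile, 61 with total counts, 68 without a filter, 497 with DESeq2, 21 with limma-voom, 69 with the number as a block, 18 with only the 6 libraries compared, 1 to 70 with libraries left out, 1080 without corpus line 8028 and 2 without the 2 antral vehicle libraries. In inhibited libraries it gave 3 with upper quartile, 3 with total counts, 16 without a filter, 149 with DESeq2, 37 with the number as a block, 0 with only the 6 libraries compared (13 with limma-voom and 1493 at an unadjusted p of 0.05 in all libraries), 0 to 1883 with libraries left out and 2386 without corpus line 8028. Of 116 list tests 31 passed, 0 with an estimated correlation, and 30 with fry, 18 of them in both camera and fry; of the 87 without the regional comparison 25 passed, 29 with the block and 0 with the block and an estimated correlation. The correlation of the regional effects was 0.823 over all tested genes, where leaving out the libraries of 1 number gave 0.73 to 0.783, and 0.935 at 5 CPM or more.

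Many of the named genes were chosen because they passed in these same data, which favours kept calls. Of all calls, with both libraries of a line left out, corpus kept fewest without line 8026 (2533 of 4985). Antrum kept fewest without line 8025 (2671 of 4794). Over 2255 values of named genes under alternatives, 2009 kept direction and side of the threshold, 190 lost the call, 43 gained it and 13 changed sign, each without passing in either setting. Chga in corpus read -0.055, and -0.055 to 1.244 over libraries left out. Chga in antrum read 0.007, 0, 0.002, 0.053, 0.012, 0.358, 0.169, 0.416, 0.189, 0.125, and -0.864 to 0.416 over libraries left out. Atp4a between regions in vehicle read 0.101, and -0.883 to 0.101 over libraries left out. Onecut2 between regions in vehicle read -0.265, and 0.109 to 0.745 over libraries left out. Lists that turned sign passed in neither setting, except that hypoxia genes in the difference between regions reached an adjusted p of 0.0031 without the 2 antral vehicle libraries, and an adjusted p = 0.649 there with an estimated correlation. With the fry test their adjusted p were 0.932, 0.954, 0.921, 0.893, 0.944. With the block their adjusted p were 0.969, 0.359. With the block and an estimated correlation their adjusted p were 0.978, 0.644. With corpus line 8028 left out their adjusted p were 0.995, 0.811, 0.982, 0.824, 0.837, 0.824, 0.995, 0.914, 0.985, 0.84, 0.995, 0.985. The other adjusted p with the antral vehicles left out were 0.977, 0.688, 0.434, 0.764, 0.871, 0.871, 0.918, 0.904, 0.904. With the block, no other call of a list turned than those given for squamous, p53 and antral identity genes. With 3 libraries per group, changes of 1.5-fold in well-counted genes were recovered in 50.7% of cases simulated for the corpus comparison, without differences between lines.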

Other observations

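The tests in these paragraphs were chosen after the results were seen.

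In corpus, 3 of 10 squamous genes rose, including Krt13 (log2 change 2.14 ± 0.263 SE) and Krt4 (1.68 ± 0.344), and 4 adjusted over the list alone, with a camera adjusted p of 0.0491, an adjusted p = 0.5 with an estimated correlation and 0.0585 with RLE scaling. Corpus intestinal genes rose in 3 of 12 cases, with Clca1 at 4.02 ± 0.486 (3 rose and 1 fell adjusted over the list alone; adjusted p 0.0451; adjusted p = 0.497 with an estimated correlation; 0.0533 with RLE scaling). Hypoxia and glycolysis genes rose in 4 of 14 cases in each region, also adjusted over the list alone, with Slc2a1, a glucose transporter, at 0.65 ± 0.082 in corpus and 0.49 ± 0.082 in antrum; the list had an adjusted p of 0.0474 and 0.0451, an adjusted p = 0.733 with an estimated correlation in both, 0.24 and 0.217 with fry, and 0.0563 and 0.0533 with RLE scaling. With line as a block, squamous genes passed in antrum (adjusted p 0.0125 in place of 0.0623), p53 targets in corpus (0.0345 in place of 0.0775) and antral identity genes in both regions (0.0325 and 0.0345 in place of 0.195 and 0.229); each of these had an adjusted p = 0.638 with the block and an estimated correlation, and with fry, run without the block, they stood at 0.00723, 0.104, 0.105 and 0.113. In corpus the block raised the squamous genes that rose from 3 to 6 and the intestinal genes from 3 to 7, with 1 intestinal gene falling. Col14a1, a fibril-associated collagen, fell in both regions, at -5.66 ± 0.978 and -6.10 ± 1.01 on the log2 scale. Its vehicle libraries varied widely, at 7.53, 24.1 and 4.06 CPM in corpus and 8.26, 4.28 and 24.3 in antrum. Ifitm3, an interferon-induced gene, fell 31.6-fold in corpus. In antrum it was lower in every line, at 2.04 to 4.63 CPM in inhibited against 43.3 to 76.5 in vehicle libraries.

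Targets of the aryl hydrocarbon receptor (Cyp1a1, Cyp1b1, Ahrr, Tiparp and Nqo1, which also answers to NRF2) rose with inhibition in both regions, and 5 of 5 kept their call in each region under RLE, upper quartile and total-count scaling, with a lowest log2 change of 0.825, which argues against library scaling as the cause. For the 6 NRF2 genes of the list scaling may account for part of the rise: total counts, which lowered the median change of all genes to -0.193 in corpus, kept 2 of 6 corpus and 2 of 3 antral calls, with a lowest log2 change of 0.235 ± 0.118 for Gclm in place of 0.394 ± 0.126. A rise of the receptor targets graded with the loss of Wnt target expression would give a negative correlation of their means over the 6 inhibited libraries, if the lines had equal levels in vehicle. Vehicle levels were not subtracted, so differences between lines before inhibition enter r, which therefore does not decide. Centred by region r was 0.931, opposite in sign and not resolved (exact permutation within region, two-sided p 0.0833, adjusted over 2 gene sets 0.167, with 0.0278 the smallest such p). Without centring r was 0.928 (exact permutation p 0.00139, adjusted 0.00278; rho = 1, p 0.00278; r 0.951 without the 2 libraries farthest from the median), and for all 11 genes of the list it was -0.317 (p 0.549; rho = -0.143, p 0.803; 0.755 without those 2). A direct effect of the compound, which the labels give at a dose far above the usual, or of the medium cannot be told apart from Wnt loss, because 0 libraries received XAV939 without the Noggin and medium change, or the reverse.

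Cholesterol synthesis genes stood higher in antral than in corpus vehicle libraries. Serum content might contribute, as corpus medium held more serum. Corpus line 8028, grown in corpus medium, lay at a median position of 0.553 between the other corpus lines and antrum (quartiles 0.423 to 0.632 over 19 of 20 genes), which does not decide. A contribution of rRNA carry-over stays open too: antral vehicle line 8026, with an rRNA-like share of 0.92%, exceeded corpus line 8028, the highest corpus vehicle library, by 0.144 log2 units, within the SD of 0.153 among corpus libraries, and the other corpus lines by at least 0.369; with it as the only antral vehicle library the list had a camera adjusted p of 6.42e-07, an adjusted p = 0.58 with an estimated correlation, and Fdps stood at 0.50 (adjusted p 0.222), but 1 library cannot exclude it. Region itself stays among the open explanations.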
